A study of Mus musculus with 15 samples.

How the data were processed

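Gene expression was measured by RNA sequencing in 15 libraries of mouse C2C12 myotubes, 3 for each of 5 groups: non-treated, vehicle, and Jakyak-gamcho-tang (JGT) at 20, 100 and 500 µg/mL. Per the labels' protocols, total RNA was made into directional mRNA libraries with an MGI kit and sequenced in paired-end reads of 100 bp. Per the submitters' processing notes, the tools used were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, with the mouse genome GRCm38 (mm10). The role of each tool, the gene annotation and the strand option of the counting are not given in the sources used here. Genes that overlap on opposite strands can therefore share counts.

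The deposited table holds the authors' expected counts per gene symbol, not normalized, with 1 column per library. Of its values, 9.34% were not whole, within a tolerance of 0.005, and all were rounded to whole numbers before testing. The table lists 42807 symbols, 19006 of which are 0 in every library. Of the symbols, 39311 matched a gene name of GENCODE M21 (GRCm38) and 31395 a RefSeq symbol, with 1508 more matched to RefSeq synonyms only. Columns were matched to samples by the names in the labels, and groups were taken from the labels' treatment text. Every column was used. Library totals ran from 26012844 to 36854199 counts.

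Genes with enough counts for testing were kept with edgeR's filterByExpr, which left 14461 genes (14397 for the trend). Normalisation used TMM factors, which lay between 0.988 and 1.02. All 15 libraries entered 1 edgeR quasi-likelihood fit with robust dispersions and a mean per group, so the spread between libraries was estimated from all groups. The common dispersion was 0.00282, a biological coefficient of variation of 5.31%, with 10 residual degrees of freedom. The 3 doses were compared with vehicle, vehicle with non-treated, and adjacent doses with each other. A separate fit of the 9 JGT libraries gave a slope per step of dose rank, with 7 residual degrees of freedom. All p-values for genes are from edgeR's two-sided quasi-likelihood F test, and a gene was called when its Benjamini-Hochberg adjusted p was below 0.05. CPM values are counts scaled by TMM to a common library size, as mean ± SD of 3 libraries, and log2 fold changes are given with the standard error of the fit or alone.

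The naming rule, the 41 gene lists, the tests of genes and lists and all alternatives but those named below as added were fixed before the data were examined. By the rule, the text names the 8 genes with the largest rise and the 8 with the largest fall in each comparison with a control (6 and 6 for the trend), among called genes with a mean CPM of at least 5, a proper gene symbol and no overlap between the 2 groups. It also names 14 fixed genes and, for each list mentioned, its 4 members with the smallest p. Which lists are mentioned was chosen after their results were seen. Lists with at least 5 tested members were tested with camera on limma-voom values with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation stands beside it. At the preset correlation, 13, 14, 14 and 14 lists were called for vehicle against non-treated and for JGT 20, 100 and 500 µg/mL against vehicle, and 18 of 40 for the trend. With an estimated correlation the counts were 1, 4, 7, 8 and 0, and for the trend 7 lists had an unadjusted p under 0.05 while 19 were called by fry, which tests whether a list's genes move on balance in 1 direction. Cyp1a1, with at most 3 counts in some groups, was described by summed counts, with an exact interval of their ratio or, against 0, a floor of 3 counts over the group. With Cyp1a1 at that bound, the median of the aryl hydrocarbon receptor list stayed at 1.70 at 500 µg/mL and 0.96 for the trend.

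The tests of genes and lists were tested on simulated data drawn from the real genes' means, dispersions and library sizes, with 200 genes changed by known amounts. For the trend, the change was set per dose step and alike for each step. Its change from 20 to 500 µg/mL was therefore larger than the size named, so its shares do not compare with those of the groups. At a log2 change of 1, the test recovered 91.0% of changed genes for vehicle against non-treated, 89.6% for JGT 20 and for JGT 100 against vehicle, 86.6% for JGT 500 against vehicle, 88.1% for JGT 100 against JGT 20, 82.1% for JGT 500 against JGT 100 and 98.5% for the trend. At a log2 change of 0.5 the shares were 74.6%, 73.1%, 68.7%, 79.1%, 68.7%, 77.6% and 88.1%, in the order vehicle against non-treated, JGT 20, 100 and 500 against vehicle, 100 against 20, 500 against 100, and trend. Of the genes called in these simulations, 6.95%, 6.99%, 2.27%, 5.38%, 5.08%, 2.29% and 3.55% were not among the changed ones, in the same order, so that 3 of the 7 shares lay within 5% and 4 above it. Of 5 simulated lists of changed genes, 5 were called, and of 5 lists of unchanged genes, 0. The simulated genes were drawn independently of each other, so these lists do not test the preset inter-gene correlation. In the real libraries, other splits of JGT 500 and vehicle called up to 15 lists, although such splits keep part of the real difference.

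The alternatives were other scaling (RLE, library totals), no low-count filter or a CPM filter, DESeq2 and limma-voom as tests, only the 6 libraries compared, non-treated or both controls, the replicate number as a block, a minimum log2 change of 1, vehicle added to the trend, a slope on the dose itself, an estimated correlation or fry for lists, separate controls for the correlation of doses, and leaving out each library in turn. Other splits of the libraries into groups of the same sizes were also fitted, all of them for 3 against 3 libraries and 100, the real one included, for the trend. The lists without JGT 500 replicate 2, and the simulated correlation of doses over genes with a CPM of at least 1, were added after seeing the data. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.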

Results

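C2C12 is a mouse myoblast line whose cells fuse into multinucleated myotubes when they differentiate. Libraries for mRNA sequencing were made from C2C12 myotubes after 6 days of differentiation and 24 h under 1 of 5 conditions. The conditions were no treatment, vehicle (0.1% DMSO), or Jakyak-gamcho-tang (JGT) at 20, 100 or 500 µg/mL. JGT is a hot-water extract of peony root and licorice root. Each condition had 3 libraries, 15 in all. The series as a whole concerns muscle wasting caused by dexamethasone, a synthetic glucocorticoid, but the labels of these libraries name no dexamethasone, so the comparisons ask what JGT alone does to myotubes at each dose. The highest dose was the one calculated to leave 80% of cells viable. Diluted from the stock that the labels describe, the 20 and 100 µg/mL doses would carry 0.004% and 0.02% DMSO and only the highest dose the 0.1% of the vehicle; whether more DMSO was added is not given in the sources used here. The sample codes of the 6 control libraries belong to a different series from those of the 9 JGT libraries. The titles of all 15 libraries begin with the same batch label, Batch1. A difference between JGT and control libraries alone can still not be told apart from a difference between these code series. Differences between doses can, although DMSO may rise with the dose. The labels do not state that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

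Total expected counts per library ran from 26012844 to 36854199, with a median of 29613890. The JGT 100 µg/mL libraries were deepest, at 35.4 ± 2.35 M counts (SD, n = 3), against 28.4 ± 2.10 M for vehicle. Between 13891 and 14372 genes had a count of 10 or more. Within a group, the mean chi-square per gene between a pair of libraries lay between 2.02 and 35.6, where sampling noise alone gives about 1, so all 15 were kept as separate samples. It was 8.50 to 35.6 within JGT 500 µg/mL, 2.02 to 4.14 within vehicle and 3.91 to 6.70 within JGT 100 µg/mL. The spread fitted over all groups may therefore be too small for JGT 500 µg/mL and too large for vehicle and JGT 100 µg/mL. A gene not called at a lower dose is thus not shown to be unchanged. The first principal component held 32.3% of the variance and placed the JGT 500 µg/mL libraries at 37.2, 17.5 and 39.4, with every other library at −0.984 or below. JGT 500 replicate 2, at 17.5, lay apart from its group, at −25.7 on the second component, where replicates 1 and 3 lay at 4.65 and 8.94. Mitochondrially encoded genes took 4.94% of the counts in that library, 4.27% in replicate 1 and 3.47% in replicate 3, against 4.88 ± 0.117% in vehicle.

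**Figure D1:**
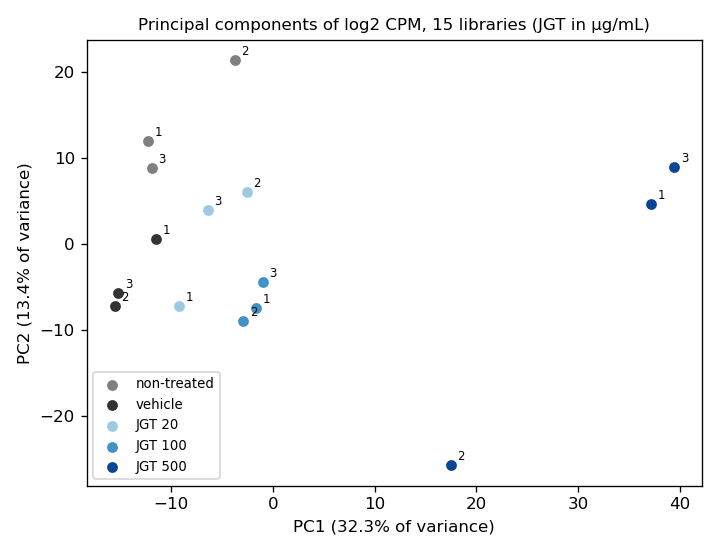
Principal components of log2 CPM of the 15 libraries, with the first component (32.3% of variance) on the x axis and the second (13.4%) on the y axis; each point is 1 library, coloured by group. The 3 JGT 500 µg/mL libraries lie to the right, and replicate 2 of that group lies lowest on the second component, at −25.7.

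At 500 µg/mL, many genes that metabolise foreign compounds or counter oxidants rose over vehicle. Gsta1 and Gsta4, glutathione S-transferases that conjugate electrophiles, rose 17.2-fold and 9.24-fold (log2 4.10 ± 0.126 and 3.21 ± 0.0804, SE). Aldh3a1, an aldehyde dehydrogenase, rose from 6.04 ± 0.221 to 85.3 ± 8.20 CPM (SD, n = 3), or 14.1-fold. Nqo1, which reduces quinones, rose from 4.04 ± 0.749 to 27.3 ± 3.50 CPM, and Cyp1b1, a cytochrome P450 that oxidises aromatic compounds and steroids, from 59.2 ± 2.49 to 331 ± 6.26 CPM. Xdh, the purine-degrading xanthine dehydrogenase, rose 4.57-fold, Mal, a membrane raft proteolipid, 4.34-fold, and Slc5a5, the sodium-iodide symporter, 3.36-fold. The adjusted p of these 8 genes, chosen by the naming rule, was 1.29e-10 for Slc5a5 and smaller for the other 7. Targets of NRF2, the transcription factor of the antioxidant response, rose together: 27 of the 34 measured members rose, 6 were not called, and Akr1b8, an aldo-keto reductase, fell (log2 −0.26, adjusted p = 0.000181). Adjusted over the list alone, 29 rose and 1 fell. The list's median log2 fold change was 0.52, and its adjusted p was 2.21e-21 with the preset correlation and 4.28e-05 with an estimated correlation. Its smallest p-values after Gsta4 and Gsta1 belonged to Gstm1, a glutathione S-transferase (log2 1.46 ± 0.0576), and Pgd, an NADPH-producing enzyme of the pentose phosphate pathway (0.90 ± 0.0367). Hmox1, the heme-degrading heme oxygenase, rose 1.68-fold (adjusted p = 1.34e-06). Of 12 measured targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, 9 rose, 2 fell and Lpcat2 was not called (log2 0.27, adjusted p = 0.529). Adjusted over the list alone, the counts were again 9 and 2. The median was 1.70, with an adjusted p of 7.1e-07, or 0.00857 with an estimated correlation. Beside Cyp1b1, Aldh3a1 and Nqo1, Ugt1a6a, a glucuronosyltransferase, had the smallest p (log2 1.61 ± 0.0807). The 2 members that fell were the receptor gene Ahr itself (log2 −0.40, adjusted p = 5.74e-07) and the amino acid transporter Slc7a5 (−0.22, 0.00147). Cyp1a1, the classical target of this receptor, had 155 counts in the 3 JGT 500 µg/mL libraries and 1 in the 3 vehicle libraries, a ratio of 143 (95% exact interval 25.3 to 5677, covering counting error only). Without JGT 500 replicate 2, a setting chosen after seeing the data, 28 NRF2 targets rose and 1 fell, and 9 receptor targets rose and 2 fell. Gsta1 and the Ugt1a genes have near-identical copies or shared exons, so their counts are uncertain. In the GENCODE M21 annotation of the mouse build GRCm38, Aldh3a1 lies on chromosome 11 at 61207537 to 61218421 (+ strand), Cyp1b1 on chromosome 17 at 79701537 to 79715061 (− strand), Gsta4 on chromosome 9 at 78182774 to 78209349 (+ strand) and Nqo1 on chromosome 8 at 107388225 to 107403206 (− strand).

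**Figure D2:**
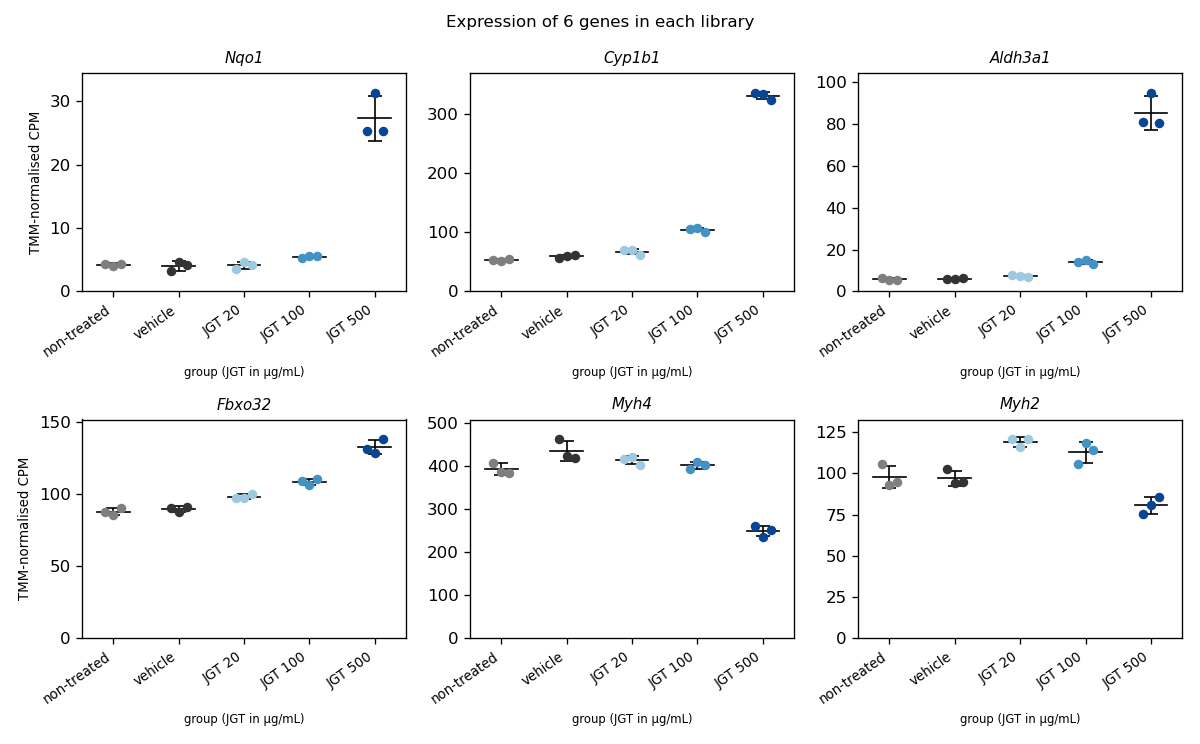
Expression in CPM (y axis) of Nqo1, Cyp1b1, Aldh3a1, Fbxo32, Myh4 and Myh2 in the 5 groups (x axis, JGT in µg/mL); points are libraries, lines are group means and bars are ± SD (n = 3). Cyp1b1 goes from 59.2 CPM in vehicle to 105 at 100 µg/mL and 331 at 500 µg/mL, while Myh4 lies at 435 CPM in vehicle and 249 at 500 µg/mL.

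Genes of cell division and of the extracellular matrix fell at 500 µg/mL. Of 40 measured cell cycle genes, 39 fell and E2f1 was not called (log2 −0.14, adjusted p = 0.278), also when adjusted over the list alone. Mki67, a marker of proliferating cells, went from 113 ± 1.83 to 42.1 ± 2.84 CPM. Ccna2, a cyclin of DNA synthesis and mitosis (log2 −1.46 ± 0.0510), Foxm1, a transcription factor of mitotic genes (−1.40 ± 0.0554), and Top2a, a DNA topoisomerase (−1.09 ± 0.0435), fell as well. The list's median was −1.18, with an adjusted p of 3.16e-39, or 4.28e-05 with an estimated correlation. Of 35 extracellular matrix and TGF-beta response genes, 21 fell, 11 were not called and 3 rose, with the same counts when adjusted over the list alone. The median was −0.36 (adjusted p = 1.24e-09, and 0.0119 with an estimated correlation). Tnc, the matrix protein tenascin C, fell from 843 ± 14.2 to 283 ± 12.7 CPM, and the actin cross-linker Tagln (log2 −1.45), the metalloproteinase inhibitor Timp3 (−0.86) and the smooth muscle actin Acta2 (−0.68) fell too. The 3 that rose were the collagen genes Col3a1 (0.51) and Col5a2 (0.21) and the matrix protein gene Mgp (0.38). Of 25 IGF, myostatin and myokine genes, 12 fell, 11 were not called and 2 rose, while 13 fell and 2 rose when adjusted over the list alone (median −0.15, adjusted p = 0.000387, and 0.00904 with an estimated correlation). Igf1, a growth factor that promotes muscle growth, fell (−1.10 ± 0.0627), as did its binding protein gene Igfbp3 (−1.69) and Fstl1 (−0.55), whereas the binding protein gene Igfbp4 rose (1.53 ± 0.0616) and so did Musk (0.28), a receptor kinase of the neuromuscular junction. The counts of Mstn, the myostatin gene, came to 7 over all 15 libraries, too few to test. By the naming rule, the genes that fell furthest were the collagen-binding Fmod (log2 −2.12 ± 0.104), the histone gene Hist1h2ap (−1.76), Sox8 (−1.69), Igfbp3, the acetylcholinesterase gene Ache (−1.69), the smooth muscle actin Actg2 (−1.68), Troap (−1.65) and Depdc1a (−1.59). The adjusted p of these 8 was at most 8.42e-08, for Hist1h2ap, whose counts are uncertain because histone genes are near copies of each other. Markers of myoblasts, reserve cells and satellite cells, the undifferentiated cells a myotube culture holds, were not called as a list (median −0.04, adjusted p = 0.0765): 3 of 20 rose, 9 fell and 8 were not called, against 4 and 9 adjusted over the list alone. Gas1, a growth arrest gene, rose (0.76), and Ccnd1, a cyclin (−0.99), Vcam1 (−0.53) and Heyl (−0.86) fell; Spry1 (0.47) and Rbl2 (0.15) were the other 2 that rose. This list was called, as lower, without JGT 500 replicate 3 (adjusted p = 0.0451). Without JGT 500 replicate 2, 39 cell cycle, 21 matrix, 14 IGF list and 10 myoblast list genes fell. Fmod lies on chromosome 1 at 134037254 to 134048277 and Ache on chromosome 5 at 137287519 to 137294466, both on the + strand.

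Muscle genes moved in both directions at 500 µg/mL. Of 43 sarcomere and contractile genes, 13 rose, 11 fell and 19 were not called (13 and 13 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.935). Its median was 0.03, while its mean, −0.04, and its test pointed down. Myh4, the fast IIb myosin heavy chain, went from 435 ± 24.0 to 249 ± 12.1 CPM (log2 −0.80 ± 0.0435). Mybpc1, a thick-filament protein (−1.05 ± 0.0508), Ckm, muscle creatine kinase (−0.48), Myh7, the slow myosin (−0.46), and Myh2, a fast myosin (−0.27 ± 0.0558, adjusted p = 0.000941), fell as well. The perinatal Myh8 fell (−0.38), but not against non-treated myotubes (−0.04, adjusted p = 0.553). The embryonic Myh3 fell by 0.18 on the log2 scale (adjusted p = 0.0455), a call lost without vehicle replicate 1 (−0.13, 0.169), vehicle replicate 2 (−0.20, 0.0651), JGT 500 replicate 1 (−0.21, 0.0571) or JGT 500 replicate 2 (−0.09, 0.126), and with library totals as the only scaling (−0.16, 0.0793). Myh1 lay at 0.01 (adjusted p = 0.879) and Ppargc1a, a coactivator of mitochondrial genes, at −0.51 (0.068). Myog, the transcription factor myogenin, rose 1.19-fold (adjusted p = 1.19e-05). The ubiquitin ligases of muscle atrophy, Fbxo32 (atrogin-1) and Trim63 (MuRF1), rose 1.48-fold (2.71e-10) and 1.25-fold (0.000129). Their list was not called (median 0.08, adjusted p = 0.0688), with 7 of 20 up, 2 down and 11 not called, also when adjusted over the list alone. Fbxo40, another muscle ubiquitin ligase, rose (0.93 ± 0.0547), and the 2 that fell were Asb2 (−0.79) and Foxo1 (−0.41). Fkbp5, a glucocorticoid-induced gene, lay at −0.13 (adjusted p = 0.191). Of 19 genes of the neuromuscular junction and the denervation response, 6 rose, 7 fell and 6 were not called, also when adjusted over the list alone. The list was not called (adjusted p = 0.973), with a median of 0.03 and a mean of −0.12. Ache, Colq, which anchors that enzyme (−0.68), and the acetylcholine receptor subunit Chrne (−1.20) fell, whereas Gadd45a rose (0.79). Autophagy genes rose: 16 of 21 rose and 5 (Gabarap, Atg3, Atg4b, Wipi1 and Tfeb) were not called, also when adjusted over the list alone. Their median was 0.24 (adjusted p = 7.1e-07, and 0.00845 with an estimated correlation), with Bnip3 (0.66), Nbr1 (0.31), Sqstm1 (0.52) and Map1lc3b (0.29) leading. Of 31 proteasome subunit genes, 14 rose and 17 were not called, and 16 rose when adjusted over the list alone (median 0.12, adjusted p = 0.000387, but adjusted p = 0.243 with an estimated correlation), led by Psma5 (0.32), Psma7 (0.25), Psmd4 (0.19) and Psmd7 (0.30). Against non-treated myotubes the proteasome list was not called (adjusted p = 0.0761), whereas the atrophy list was (0.0361). Relative to vehicle, the sarcomere median was 0.06 and 0.05 in JGT 500 replicates 1 and 3 and −0.04 in replicate 2, and the autophagy median was 0.25, 0.22 and 0.18 in the same order. Without replicate 2, 14 sarcomere genes rose and 12 fell, 8 atrophy list genes rose and 3 fell, 6 junction genes rose and 8 fell, 16 autophagy genes rose, and 18 proteasome genes rose and 2 fell. Myh4 lies on chromosome 11 at 67238029 to 67260446 (+ strand) and Fbxo32 on chromosome 15 at 58175879 to 58214932 (− strand).

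Hypoxia response genes rose at 500 µg/mL, where 10 of 20 rose and 10 were not called, and 11 rose when adjusted over the list alone. Their median was 0.19 (adjusted p = 2.75e-05, and 0.0207 with an estimated correlation), and Bnip3, the oxygen sensor gene Egln3 (0.43), the glucose transporter gene Slc2a1 (0.40) and the adenylate kinase gene Ak4 (0.85) had the smallest p-values. Adipocyte markers, a list kept for cells of another type, also rose: 5 of 7 measured markers rose, Agt fell (−1.10, adjusted p = 0.00271) and Dgat2 was not called (0.18, 0.318), also when adjusted over the list alone. Their median was 0.51 (adjusted p = 0.0121, but adjusted p = 0.126 with an estimated correlation), and the 5 were Lpl (2.83-fold), Cebpa (0.55), Lipe (0.51), Plin4 (0.65) and Pparg (0.27). Of 24 immediate early genes, 13 fell, 10 were not called and 1 rose, and 13 fell and 2 rose when adjusted over the list alone (median −0.22, adjusted p = 0.00213, but adjusted p = 0.168 with an estimated correlation). Against non-treated myotubes the list was not called (adjusted p = 0.115). Fosb (−0.94), Junb (−0.36) and Nr4a1 (−0.51) fell and Fosl2 rose (0.42). Across the transcriptome, 4815 of 14461 tested genes were called, 2387 higher and 2428 lower, and 391 of them changed by a log2 of at least 1 (126 higher, 265 lower). With library totals as the only scaling, 2697 were higher and 2217 lower. Members named because a count was 5 or fewer were chosen after their values were seen. Genes named by rank also had to show no overlap between the 3 JGT and 3 vehicle libraries, which chance alone gives for 10% of genes. Without JGT 500 replicate 2, 11 hypoxia genes rose, 5 adipocyte markers rose and 1 fell, and 1 immediate early gene rose and 14 fell.

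**Figure D3:**
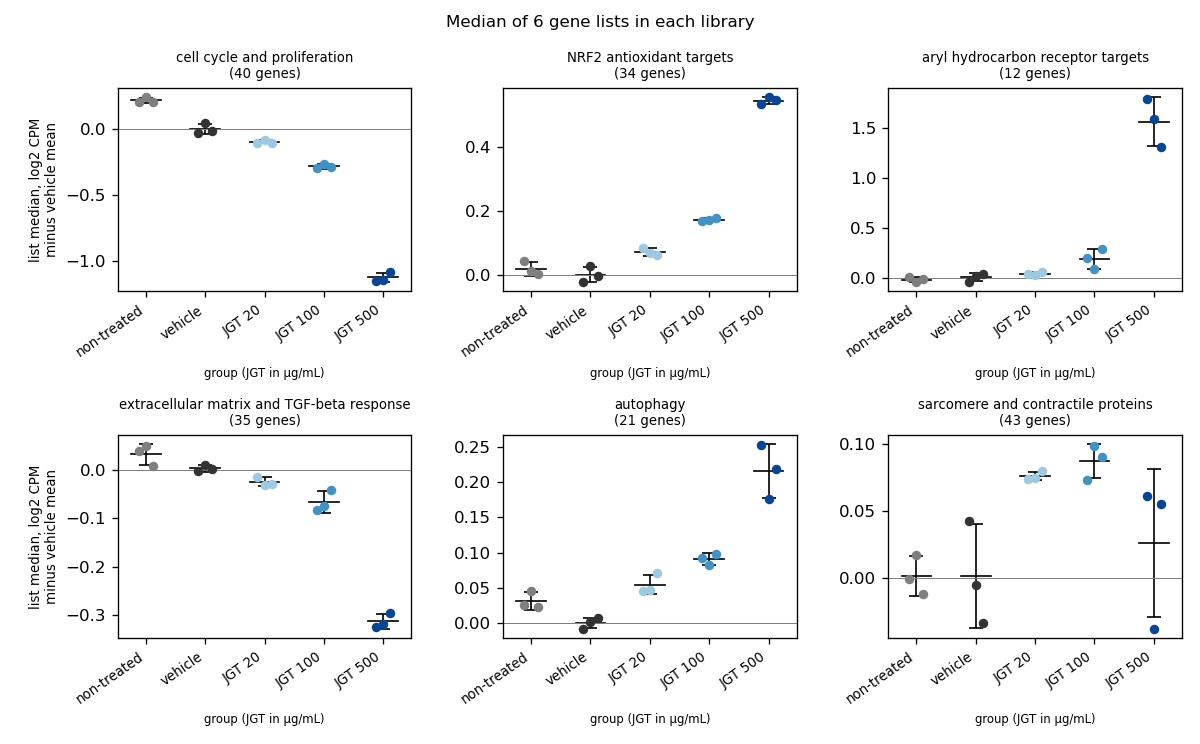
Median log2 difference from the vehicle mean (y axis) over the measured members of 6 gene lists, for each library by group (x axis, JGT in µg/mL); points are libraries, lines are group means and bars are ± SD (n = 3). The cell cycle medians fall and the NRF2 medians rise with the JGT dose, and the JGT 500 µg/mL libraries lie farthest from 0 in both.

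At 100 µg/mL the medians of the cell cycle, NRF2, receptor and matrix lists lay nearer to 0 than at 500 µg/mL. By the naming rule, Greb1, an estrogen-responsive gene, rose most, from 5.76 ± 0.605 to 17.0 ± 0.163 CPM (2.94-fold, adjusted p = 1.76e-10), and it lay at 13.0 ± 0.607 CPM at 500 µg/mL. Aldh3a1 rose 2.32-fold, Slc5a5 2.26-fold, Lars2, the mitochondrial leucyl-tRNA synthetase gene, 1.98-fold, Csf2rb, a cytokine receptor subunit, 1.92-fold, Mal 1.79-fold, Cyp1b1 1.77-fold and Xdh 1.76-fold. The imprinted gene Mest (log2 −0.59), the fatty acid-binding Fabp5 (−0.56), Fmod (−0.55), the Notch-modifying Lfng (−0.54), Sox8 (−0.53), the lipid transporter Mfsd2a (−0.52), the receptor Gfra1 (−0.52) and the growth factor Pdgfb (−0.52) fell furthest. Of 40 cell cycle genes, 25 fell and 15 were not called, and 34 fell when adjusted over the list alone (median −0.30, adjusted p = 7.67e-34, and 0.00017 with an estimated correlation). Foxm1 (−0.40), Ccna2 (−0.36), Cdc20 (−0.47) and Kif20a (−0.33) led them. Of 34 NRF2 targets, 13 rose and 21 were not called, while 16 rose and 1 fell when adjusted over the list alone (median 0.14, adjusted p = 4.13e-14, and 0.000174 with an estimated correlation), led by Gstm1 (0.63), the ferritin gene Fth1 (0.39), the aldehyde oxidase gene Aox1 (0.46) and Pgd (0.27). Hmox1 rose (0.39, adjusted p = 0.00704) and Nqo1 lay at 0.45 (0.057). Of 12 aryl hydrocarbon receptor targets, 3 rose (Cyp1b1, Aldh3a1 and Ugt1a6a, log2 0.53), Ahr fell (−0.20) and 8 were not called, while 5 rose and 1 fell when adjusted over the list alone. The median was 0.30, or 0.15 without Cyp1a1, which had 2 counts in these 3 libraries, and the adjusted p was 2.89e-05, or 0.0273 with an estimated correlation. Of 20 hypoxia genes, 5 rose and 15 were not called, while 6 rose and 1 fell when adjusted over the list alone (median 0.13, adjusted p = 4.74e-05, and 0.0338 with an estimated correlation). They were Egln3 (0.29), Bnip3 (0.26), Slc2a1 (0.18), Mxi1 (0.21) and Vegfa (0.13). Of 35 matrix genes, 9 fell, 25 were not called and the proteoglycan gene Dcn rose (0.27), while 12 fell and 1 rose when adjusted over the list alone (median −0.06, adjusted p = 1.19e-05, but adjusted p = 0.0575 with an estimated correlation). Tagln (−0.38), Timp3 (−0.31), Tnc (−0.32) and Ctgf (−0.42) led them. Of 38 genes of the integrated stress response and amino acid synthesis, 4 rose, 1 fell and 33 were not called, while 9 rose and 1 fell when adjusted over the list alone (median 0.11, adjusted p = 5.63e-07, but adjusted p = 0.0675 with an estimated correlation). Vldlr (0.41), Psat1 (0.20), Slc6a9 (0.25) and Slc3a2 (0.16) rose and the amino acid transporter gene Slc7a1 fell (−0.27). Of 43 sarcomere genes, 5 rose and 38 were not called, while 11 rose and 2 fell when adjusted over the list alone (median 0.09, adjusted p = 3.12e-05, but adjusted p = 0.238 with an estimated correlation). The 5 were Myom3 (0.17), Tnnt3 (0.18), Myh2 (0.22), Actn2 (0.14) and Smpx (0.15). Fbxo32 rose 1.21-fold (adjusted p = 0.000118). Trim63 (0.01, adjusted p = 0.981), Myh1 (0.08, 0.493), Myh3 (0.00, 0.991), Myh4 (−0.11, 0.162), Myh7 (−0.06, 0.719), Myog (0.08, 0.235), Ppargc1a (−0.17, 0.76) and Fkbp5 (−0.05, 0.839) were not called. In all, 623 genes were called, 302 higher and 321 lower (264 and 388 with library totals as the only scaling), 24 of them by a log2 of at least 1. With that scaling Actn2 was not called (adjusted p = 0.0639). A fit of the 6 libraries alone called 1369 genes, both controls together gave 1144, and non-treated myotubes as the control 1320, 430 of them shared with the 623. Leaving out 1 library gave 401, 365 or 315 calls without vehicle replicate 1, 2 or 3 and 357, 351 or 409 without JGT 100 replicate 1, 2 or 3. Leaving out 1 library also ended calls of some of these genes, with fewer libraries left to test them. Actn2, not called whichever library was left out, then lay between 0.12 and 0.16, against 0.14 with all libraries. Without vehicle replicate 1, the adjusted p was 0.0637 for Tnnt3, 0.0731 for Actn2, 0.057 for Slc2a1 and 0.0932 for Mxi1. Without vehicle replicate 2, it was 0.129 for Myh2, 0.0787 for Myom3, 0.066 for Tnnt3, 0.0582 for Actn2 and 0.0703 for Ahr. Without vehicle replicate 3, it was 0.0959 for Fabp5, 0.0538 for Sox8, 0.14 for Myh2, 0.153 for Myom3, 0.138 for Tnnt3, 0.191 for Actn2, 0.0569 for Slc2a1 and 0.111 for Mxi1. Without JGT 100 replicate 1, it was 0.115 for Actn2, 0.0668 for Ahr and 0.0643 for Mxi1. Without JGT 100 replicate 2, it was 0.0512 for Fabp5, 0.156 for Myh2, 0.106 for Myom3, 0.188 for Tnnt3, 0.0967 for Actn2, 0.0693 for Slc6a9 and 0.0957 for Mxi1. Without JGT 100 replicate 3, it was 0.0536 for Fabp5, 0.106 for Myh2, 0.0656 for Myom3, 0.0871 for Actn2 and 0.0502 for Slc2a1. With non-treated myotubes as the control, Sox8 (−0.17, adjusted p = 0.405), Tnnt3 (0.12, 0.122), Psat1 (0.07, 0.221), Bnip3 (0.11, 0.266) and Slc2a1 (0.12, 0.0544) were not called, nor were the hypoxia list (adjusted p = 0.674) and the stress response list (0.0609).

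At 20 µg/mL, 47 genes were called against vehicle. Lars2 rose 1.96-fold (163 ± 18.7 to 320 ± 10.9 CPM), Greb1 1.51-fold and the mitochondrial ribosomal RNA mt-Rnr2 1.37-fold. The Notch target Hes1 (log2 0.39), the BMP antagonist Grem1 (0.30), the transcription factor E2f2 (0.30), the signalling inhibitor Spry1 (0.30) and Myh2 (0.30) rose too. By the naming rule, Txnip, which binds thioredoxin, fell most (−0.44 ± 0.0472, adjusted p = 6.98e-05), followed by Mest (−0.41), Mfsd2a (−0.41), Rem1 (−0.39), Erf (−0.34), Pdgfb (−0.29), the hyaluronan receptor Cd44 (−0.29) and the sterol carrier Stard4 (−0.28). Of 40 cell cycle genes, 0 were called by edgeR or limma-voom and 1 by DESeq2, with 17 at an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, 9 fell, and the list as a whole fell (median −0.11, adjusted p = 8.8e-10, and 0.0283 with an estimated correlation). Foxm1 lay at −0.23 (adjusted p = 0.0648), Ccna2 at −0.19 (0.0892), Ccnb1 at −0.27 (0.105) and Cdc20 at −0.24 (0.105). Of 34 NRF2 targets, Me1, the NADP-dependent malic enzyme gene, rose (0.23) and 33 were not called, while 8 rose when adjusted over the list alone (median 0.06, adjusted p = 0.000545, and 0.0413 with an estimated correlation). Gstm1 lay at 0.24 (adjusted p = 0.0903), Gstp1 at 0.15 (0.105) and Pgd at 0.14 (0.119). Of 20 hypoxia genes, Slc2a1 rose (0.19) and 19 were not called, while 4 rose when adjusted over the list alone (median 0.07, adjusted p = 1.59e-05, and 0.0413 with an estimated correlation). Ak4 lay at 0.43 (adjusted p = 0.0838), Egln3 at 0.16 (0.0929) and Bnip3 at 0.19 (0.167). Of 43 sarcomere genes, Myh2 rose and 42 were not called, while 3 rose when adjusted over the list alone (median 0.08, adjusted p = 4.61e-07, but adjusted p = 0.133 with an estimated correlation). Smpx lay at 0.16 (adjusted p = 0.123), Mybpc2 at 0.24 (0.134) and Tnnt3 at 0.12 (0.362). Fbxo32 (0.13, adjusted p = 0.162), Trim63 (−0.03, 0.879), Myh1 (0.12, 0.415), Myh3 (0.07, 0.746), Myh4 (−0.07, 0.594), Myh7 (0.08, 0.705), Myog (0.09, 0.348), Ppargc1a (−0.05, 0.961), Nqo1 (0.03, 0.951), Hmox1 (0.15, 0.525), Cyp1b1 (0.18, 0.11) and Fkbp5 (0.04, 0.885) were not called. Of the 47 genes called, 25 were higher and 22 lower, and 1 of them changed by a log2 of at least 1, the translation elongation factor gene Eef1a2 (1.06), chosen after its value was seen. The count rests on the fit and the control: 95 genes were called by DESeq2, 73 without a low-count filter, 330 in a fit of the 6 libraries alone, 196 against both controls together, and 450 (172 higher, 278 lower) against non-treated myotubes, 31 of them shared with the 47. Leaving out 1 library gave 27, 19 or 18 calls without vehicle replicate 1, 2 or 3 and 20 or 22 without JGT 20 replicate 1 or 2. Any of the 6 libraries, left out alone, ended the calls of Mfsd2a and Me1, whose adjusted p was 0.132 and 0.0914 without vehicle replicate 1, 0.255 and 0.118 without replicate 2, and 0.163 and 0.249 without replicate 3. Without JGT 20 replicate 1, 2 or 3, it was 0.0971, 0.264 or 0.0973 for Mfsd2a and 0.0971, 0.204 or 0.12 for Me1. Without vehicle replicate 1, the adjusted p was 0.13 for Spry1, 0.112 for Pdgfb, 0.0707 for Stard4 and 0.182 for Slc2a1. Without vehicle replicate 2, it was 0.0732 for Lars2, 0.137 for Myh2, 0.231 for Rem1, 0.0548 for Erf, 0.137 for Pdgfb and 0.142 for Stard4. Without vehicle replicate 3, it was 0.108 for Lars2, 0.146 for Spry1, 0.149 for Myh2, 0.162 for Rem1, 0.166 for Pdgfb, 0.138 for Stard4 and 0.169 for Slc2a1. Without JGT 20 replicate 1, it was 0.0638 for Lars2, 0.079 for Spry1, 0.0981 for Myh2, 0.168 for Rem1, 0.156 for Pdgfb, 0.115 for Stard4 and 0.0653 for Slc2a1. Without JGT 20 replicate 2, it was 0.0589 for Lars2, 0.166 for Spry1, 0.0636 for Myh2, 0.184 for Rem1, 0.204 for Pdgfb, 0.162 for Stard4 and 0.184 for Slc2a1, and without JGT 20 replicate 3, 0.0949 for Myh2 and 0.112 for Slc2a1. With non-treated myotubes as the control, Grem1 lay at −0.05 (adjusted p = 0.664), and Mfsd2a (−0.25, 0.147), Rem1 (−0.19, 0.245), Me1 (0.09, 0.338) and Slc2a1 (0.13, 0.0645) were not called. Against that control, the NRF2 list (adjusted p = 0.0518) and the hypoxia list (0.832) were not called either. By limma-voom the adjusted p was 0.0521 for Mfsd2a, 0.0506 for Rem1 and 0.0643 for Me1, and with library totals as the only scaling 0.0522 for Pdgfb.

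Mitochondrial ribosomal RNA was higher in JGT than in vehicle libraries at every dose. Its share of all counts was 0.280 to 0.288% in the 3 vehicle libraries, 0.286 to 0.339% in non-treated, and 0.385 to 0.400%, 0.418 to 0.438% and 0.405 to 0.446% at 20, 100 and 500 µg/mL. For mt-Rnr2, log2 fold changes over vehicle were 0.45, 0.58 and 0.57 (adjusted p = 6.98e-05, 1.76e-07 and 8.13e-09), and for Lars2 0.97, 0.98 and 1.12 (0.0131, 0.00184 and 7.34e-05). For mt-Rnr1 they were 0.49, 0.65 and 0.52, and the value at 20 µg/mL was not called (adjusted p = 0.162, 0.0129 and 0.00795). The 3 genes did not pass the trend test over JGT doses (adjusted p = 0.905 for mt-Rnr1, 0.138 for mt-Rnr2 and 0.478 for Lars2). Replication-dependent histones, a list kept as a sign of RNA without a poly(A) tail, were lower as a list at 20 µg/mL (median −0.18, adjusted p = 0.0439, but adjusted p = 0.263 with an estimated correlation). That call was lost against non-treated libraries (adjusted p = 0.896) and without vehicle replicate 3 (0.178), JGT 20 replicate 1 (0.127) or JGT 20 replicate 3 (0.118). Of its 7 measured members, 0 were called by edgeR, limma-voom or DESeq2, with 1 at an unadjusted p under 0.05 in edgeR and 1 lower when adjusted over the list alone. Hist1h1c lay at −0.18 (adjusted p = 0.105, but −0.23 and 0.0432 without JGT 20 replicate 2), Hist1h1e at −0.50 (0.543), Hist1h1d at −0.48 (0.688) and Hist2h2aa1 at −0.76 (0.838). Nuclear copies of mitochondrial sequences make the counts of mt-Rnr1 and mt-Rnr2 uncertain. Whether the counts of Lars2, which also rose by about the same size at every dose, come from its own mRNA was not tested.

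Comparisons between JGT doses, which lie within 1 code series, asked which genes differed between doses. By dilution of the stock, the 20, 100 and 500 µg/mL doses carry 0.004%, 0.02% and 0.1% DMSO. Unless DMSO was added to the lower doses, it may be part of these differences. Vehicle against non-treated libraries tests 0.1% DMSO alone, and edgeR called 0 of the 13 fixed genes tested. Log2 changes there were −0.07 for Nqo1, 0.16 for Cyp1b1, −0.01 for Myh2 and 0.15 for Myh4, with SEs of at most 0.139. From 100 to 500 µg/mL these genes changed far more, which argues against DMSO alone as the cause for them. For other genes, and for DMSO acting together with JGT, the effects cannot be told apart here. From 20 to 100 µg/mL, 62 genes were called, 43 higher and 19 lower, or 38 and 30 with library totals as the only scaling, and 191 in a fit of these 6 libraries alone. Of the genes fixed in advance, Cyp1b1 rose (log2 0.64 ± 0.0452, adjusted p = 1.13e-07), while Nqo1 (0.41, 0.236), Hmox1 (0.24, 0.287), Fbxo32 (0.14, 0.1), Trim63 (0.04, 0.969), Myh1 (−0.04, 0.969), Myh2 (−0.08, 0.867), Myh3 (−0.07, 0.946), Myh4 (−0.04, 0.946), Myh7 (−0.14, 0.608), Myog (−0.01, 0.994), Ppargc1a (−0.13, 0.971) and Fkbp5 (−0.09, 0.917) were not called. Leaving out 1 library gave 26, 22 or 41 calls without JGT 100 replicate 1, 2 or 3 and 34, 21 or 19 without JGT 20 replicate 1, 2 or 3. From 100 to 500 µg/mL, 2853 genes were called, 1309 higher and 1544 lower, or 1748 and 1238 with library totals as the only scaling, and 1313 in all in a fit of these 6 libraries alone. Nqo1 rose 4.98-fold (log2 2.32 ± 0.107), Cyp1b1 3.17-fold, Hmox1 1.28-fold, Trim63 1.25-fold, Fbxo32 1.22-fold and Myog 1.13-fold, and Myh4 (−0.69 ± 0.0434), Myh2 (−0.49) and Myh7 (−0.39) fell. The adjusted p of these 9 genes was at most 0.00301, for Hmox1. Cyp1a1 had 155 counts at 500 µg/mL and 2 at 100 µg/mL, a ratio of 88.2 (95% exact interval 24.0 to 734.3), and was at least 53.1-fold higher than at 20 µg/mL, where it had 0, set against a floor of 3 counts over the group. Myh1 (−0.07, adjusted p = 0.382), Myh3 (−0.18, 0.0624), Ppargc1a (−0.34, 0.279) and Fkbp5 (−0.08, 0.469) were not called. Without JGT 500 replicate 2 there were 4989 calls, and without JGT 100 replicate 2 there were 1880.

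Over the 9 JGT libraries, slopes per dose step were tested. DMSO carried from the stock would rise over the same steps, unless it was added to the lower doses. A slope takes both dose steps as equal on the log2 scale, which did not hold for all genes. At 20, 100 and 500 µg/mL, Nqo1 lay at 4.15, 5.48 and 27.3 CPM and Myh4 at 414, 402 and 249 CPM. For such genes the slope is an average over unequal steps, and the misfit adds to the spread. Whether this lowered the calls of lists with an estimated correlation was not tested. By the naming rule, Gsta1 (log2 2.00 ± 0.230 per step), Aldh3a1 (1.86), Gsta4 (1.54), Nqo1 (1.46), Cyp1b1 (1.16) and Xdh (1.00) rose most steeply. Ache (−0.90), Fmod (−0.87), Hist1h2ap (−0.84), Tnc (−0.79), Actg2 (−0.76) and Pbk, a mitotic kinase (−0.68), fell most steeply, and the adjusted p of these 12 genes was at most 0.00503, for Gsta4. Of 40 cell cycle genes, 39 fell and E2f1 was not called (−0.07, adjusted p = 0.325), also when adjusted over the list alone, with a median slope of −0.52 (adjusted p = 1.94e-31, but adjusted p = 0.196 with an estimated correlation). Ttk (−0.64), Aurka (−0.55), Kif23 (−0.54) and Bub1b (−0.52) led them. Of 34 NRF2 targets, 27 rose, 6 were not called and Akr1b8 fell (−0.12), while 29 rose and 1 fell when adjusted over the list alone (median 0.26, adjusted p = 1.15e-21, but adjusted p = 0.16 with an estimated correlation), led by Fth1 (0.38), Gstm1 (0.61), Srxn1 (0.32) and Aox1 (0.33). Of 12 aryl hydrocarbon receptor targets, 9 rose, Ahr fell (−0.14), and Lpcat2 (0.00, adjusted p = 0.986) and Slc7a5 (−0.11, 0.111) were not called, while 9 rose and 2 fell when adjusted over the list alone (median 0.96, adjusted p = 5.42e-07, but adjusted p = 0.16 with an estimated correlation). Cyp1a1, with 0, 2 and 155 counts at the 3 doses, Ugt1a6a (0.76), Tiparp (0.20) and Cyp1b1 had the smallest p-values. Of 35 matrix genes, 20 fell, 13 were not called, and Col3a1 (0.21) and Thbs1 (0.13) rose, while 22 fell and 3 rose when adjusted over the list alone (median −0.16, adjusted p = 2.01e-07, but adjusted p = 0.258 with an estimated correlation). Postn (−0.26), Timp3 (−0.37), Acta2 (−0.27) and Loxl1 (−0.21) led them. Between 500 and 20 µg/mL directly, a test of these lists chosen after seeing the data, the adjusted p with an estimated correlation was 1.94e-05 for the cell cycle and NRF2 lists, 0.00459 for the receptor list and 0.0104 for the matrix list. Fbxo32 (0.22, adjusted p = 6.59e-05), Trim63 (0.18, 0.006) and Hmox1 (0.30, 0.000317) rose, and Myh2 (−0.28, 0.00154), Myh4 (−0.37, 0.00616) and Myh7 (−0.27, 0.000463) fell. Myog rose (0.08, adjusted p = 0.0466) and Myh3 fell (−0.13, 0.0379), but both calls were lost without some single libraries. For Myog the adjusted p was 0.163, 0.0954 or 0.0531 without JGT 500 replicate 1, 2 or 3, 0.0633 or 0.0564 without JGT 100 replicate 1 or 2, and 0.104 or 0.0952 without JGT 20 replicate 1 or 3. For Myh3 it was 0.0828 or 0.0601 without JGT 500 replicate 1 or 2, 0.0528 without JGT 100 replicate 1, and 0.077, 0.0801 or 0.0769 without JGT 20 replicate 1, 2 or 3, and 0.0517 with library totals as the only scaling. Myh1 (−0.06, adjusted p = 0.205), Ppargc1a (−0.23, 0.197) and Fkbp5 (−0.09, 0.166) were not called. In all, 2287 of 14397 tested genes were called, 1035 rising and 1252 falling, with 1374 without JGT 500 replicate 1 and 3892 with the vehicle libraries added as rank 0.

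Vehicle against non-treated myotubes gives the background of the vehicle itself. Genes of cell division were lower with vehicle: 15 of 40 fell and 25 were not called, and 30 fell when adjusted over the list alone (median −0.22, adjusted p = 3.06e-28, and 0.000384 with an estimated correlation). Top2a (log2 −0.37 ± 0.0415), Mki67 (−0.34), Kif20a (−0.32) and Cenpe (−0.33) led them. Of 25 cholesterol synthesis genes, 4 fell, Idi1 (−0.27), Hmgcs1 (−0.23), Fdps (−0.20) and Sqle (−0.17), and 21 were not called, while 14 fell when adjusted over the list alone (median −0.14, adjusted p = 9.82e-09, but adjusted p = 0.15 with an estimated correlation). Of 24 immediate early genes, Egr1 (0.31) and Nr4a1 (0.31) rose and 22 were not called, among them Jun (0.15, adjusted p = 0.063) and Junb (0.18, 0.0657), while 4 rose when adjusted over the list alone (median 0.13, adjusted p = 0.000705, but adjusted p = 0.15 with an estimated correlation). Among genes that pass the naming rule, Fbln7 (0.52), the myosin light chain Myl2 (0.37), Id3 (0.37), Carns1 (0.36), Nos1 (0.35), Myh8 (0.34), Colq (0.32) and Gas1 (0.32) rose most. By the same rule, Clspn (−0.48), Kif15 (−0.44), Plet1 (−0.43), Isx (−0.43), Dynap (−0.43), Polq (−0.43), Actg2 (−0.42 ± 0.0548) and Fgfbp1 (−0.41) fell most. Of the 13 fixed genes that could be tested, 0 were called by edgeR, limma-voom or DESeq2, with 4 at an unadjusted p under 0.05 in edgeR. Their adjusted p was 0.724 for Fbxo32, 0.766 for Trim63, 0.931 for Myh1, 0.945 for Myh2, 0.878 for Myh3, 0.0913 for Myh4, 0.841 for Myh7, 0.188 for Myog, 0.231 for Ppargc1a, 0.837 for Nqo1, 0.955 for Hmox1, 0.0841 for Cyp1b1 and 0.422 for Fkbp5. In all, 189 genes were called, 80 higher and 109 lower, against 319 by DESeq2 and 1031 in a fit of the 6 libraries alone. Leaving out 1 library gave 69, 88 or 51 calls without non-treated replicate 1, 2 or 3 and 36, 43 or 52 without vehicle replicate 1, 2 or 3. Leaving out 1 library ended calls here too, again with fewer libraries left to test them. Without non-treated replicate 1, the adjusted p was 0.0813 for Fbln7, 0.0612 for Kif15, 0.11 for Plet1, 0.17 for Isx, 0.0765 for Dynap, 0.156 for Polq, 0.0695 for Fdps, 0.108 for Sqle, 0.111 for Egr1 and 0.0813 for Nr4a1. With non-treated replicate 2 left out, the adjusted p was 0.0671 for Kif15, 0.104 for Isx, 0.14 for Polq, 0.148 for Fdps, 0.107 for Sqle, 0.139 for Egr1 and 0.139 for Nr4a1. Without non-treated replicate 3, the adjusted p was 0.132 for Fbln7, 0.0648 for Id3, 0.056 for Nos1, 0.0709 for Colq, 0.067 for Kif15, 0.0675 for Plet1, 0.0758 for Isx, 0.0751 for Dynap, 0.0588 for Polq, 0.0627 for Fdps, 0.118 for Sqle, 0.122 for Egr1 and 0.172 for Nr4a1. With vehicle replicate 1 left out, the adjusted p was 0.104 for Fbln7, 0.0525 for Myl2, 0.0525 for Nos1, 0.0777 for Colq, 0.0945 for Kif15, 0.103 for Plet1, 0.111 for Isx, 0.0897 for Dynap, 0.102 for Polq, 0.0525 for Idi1, 0.128 for Fdps, 0.126 for Sqle, 0.0945 for Egr1 and 0.0967 for Nr4a1. Without vehicle replicate 2, the adjusted p was 0.122 for Fbln7, 0.0664 for Id3, 0.0516 for Nos1, 0.0633 for Colq, 0.097 for Kif15, 0.0617 for Plet1, 0.155 for Isx, 0.095 for Polq, 0.131 for Fdps, 0.131 for Sqle, 0.148 for Egr1 and 0.195 for Nr4a1. With vehicle replicate 3 left out, the adjusted p was 0.101 for Plet1, 0.152 for Isx, 0.0758 for Dynap, 0.207 for Polq, 0.0794 for Fdps, 0.112 for Sqle, 0.0734 for Egr1 and 0.1 for Nr4a1. By limma-voom it was 0.0656 for Isx, 0.0505 for Fdps and 0.068 for Nr4a1, and with library totals as the only scaling 0.0522 for Fdps.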

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

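The tests of a dose-growing rise of mitochondrial ribosomal RNA, of an exchanged label and of both explanations of the cell cycle pattern were chosen only after the result was seen, as were the slopes of JGT 500 replicate 2. The tests of non-polyadenylated RNA, of a weaker response, of length bias and of other splits were not.

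Some genes were past the threshold in opposite directions at a lower dose and at 500 µg/mL against the same vehicle libraries, a choice that itself makes the difference between the doses large. Myh2 was higher at 20 and 100 µg/mL (log2 0.30 and 0.22) and lower at 500 (−0.27), a difference of −0.56 from 20 to 500 and −0.49 from 100 to 500 µg/mL. For Aldh1l2, a mitochondrial folate enzyme, these differences were −0.56 and −0.60, and for Eef1a2, at a mean of only 1.35 CPM, −1.74 and −1.60. From 100 to 500 µg/mL, Cyfip2 differed by −0.43, Errfi1 by −0.45, Gm4070 by −0.46 and Pcsk6 by −0.70. The Myh2 calls were lost at 20 µg/mL without vehicle replicate 2 or 3 (adjusted p = 0.137 and 0.149) or JGT 20 replicate 1, 2 or 3 (0.0981, 0.0636 and 0.0949), and at 100 µg/mL without vehicle replicate 2 or 3 (0.129 and 0.14) or JGT 100 replicate 2 or 3 (0.156 and 0.106). Single libraries were not left out for the other genes of this paragraph.

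The rise of mt-Rnr1, mt-Rnr2 and Lars2 over vehicle had about the same size at every dose. A response that grows with the dose is argued against as the whole cause, since the highest slope per dose step of the 3 genes was 0.0738 ± 0.0628 (SE), for Lars2, beside 0.97 over vehicle already at 20 µg/mL. More non-polyadenylated RNA in the JGT libraries stays open: Gm26917, the only tested RNA of the set written for that test, lay at 0.37 at 20 µg/mL (adjusted p = 0.532), while the histone list, which runs against it, was lower (median −0.18, adjusted p = 0.0439, but adjusted p = 0.263 with an estimated correlation, and 0.178, 0.127 and 0.118 at the preset correlation without vehicle replicate 3, JGT 20 replicate 1 or JGT 20 replicate 3). The histones do not exclude it, because 5 of the 7 had at most 2.87 CPM in vehicle (Hist2h2aa1, the highest of these 5), and because histone RNA also follows cell division, whose list was lower too (−0.11). Whether the rise belongs to JGT, which would then act in full at the lowest dose, or to the series of codes that parts JGT from control libraries cannot be told apart, because every JGT library is in 1 series. The titles of control and JGT libraries carry the same batch label, Batch1.

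JGT 500 replicate 2 lies apart from replicates 1 and 3. A weaker response to the dose in all lists is argued against, since its medians of the NRF2 and cell cycle lists were 1.03 and 1.02 times those of the other 2, although its slope over all genes was lower (0.548, against 0.731 and 0.714 for replicates 1 and 3). A length bias is argued against by a Spearman correlation across genes of −0.0446 between its deviation and exonic length (94.8% of genes had a length), and an exchange with a JGT 100 µg/mL library by the highest of those lying at −0.98 on the first component, below the 17.5 of this library. What sets the library apart, GC content included, stays open, and no biological explanation other than the weaker response was tested.

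The fall of cell cycle genes at 500 µg/mL may reflect fewer or less active dividing cells among the myotubes. A loss of all undifferentiated cells alike is not decided by the myoblast and reserve cell list. Its lower quartile, −0.41, lies above the upper quartile of the cell cycle list, −0.70. Myotubes were not measured apart from other cells, and any expression of these genes in them would dilute the list's fall. A difference between the control and the JGT series as the whole cause is argued against, since the upper quartile of the slopes within the JGT libraries was −0.33. A loss of all undifferentiated cells, a loss of the dividing cells only, and a response of the same cells to JGT all stay open. Unless DMSO was added to the lower doses, it rises with the JGT dose and may add to the slopes within the JGT libraries. The cell cycle list was also lower in vehicle, with 0.1% DMSO, than in non-treated libraries (median −0.22).

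For the trend, 1 of 100 splits of the 9 libraries, the real one, gave as many genes as 2287. The highest of the others gave 1 gene, so a chance division of these libraries is argued against. In the other splits the real dose difference adds to the spread, which lowers their counts. Chance differences between cultures are not covered, since the labels do not state that the libraries of a group came from separate cultures. For its 18 lists at the preset correlation, 4 of the 100, the real one included, gave as many, with 18 as the highest of the others. That share lies under 0.05 but close to it, and only 100 splits were fitted, so chance is not clearly excluded. With an estimated correlation, camera called 0 of the 40 lists for the trend (7 at an unadjusted p under 0.05, and 19 by fry), whereas between 500 and 20 µg/mL directly the cell cycle and NRF2 lists (adjusted p = 1.94e-05 for both), the aryl hydrocarbon receptor list (0.00459) and the matrix list (0.0104) were called with it, a test chosen after the result was seen. The comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. There the real gene counts of 189, 47, 623, 4815, 62 and 2853 stood against 1, 0, 0, 136, 1 and 343 in the highest other split, for vehicle against non-treated, JGT 20, 100 and 500 against vehicle, 100 against 20 and 500 against 100. The lists called were 13, 14, 14 and 14 in the first 4 of these comparisons, against 8, 8, 10 and 15, so that 3 of the 10 splits of JGT 500 and vehicle gave as many lists and 1 of the 10 in each of the others. Every other split divides both groups unequally, so it keeps part of the real difference and adds the rest to the spread. These counts of genes and lists therefore do not measure what is called without any effect.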

How the results depend on the processing

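Which lists, and so which of their members, are named here was chosen only after the result was seen; every alternative here was planned.

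Of 291 values of named genes, 216 were called. The alternatives counted for them were RLE, library totals, DESeq2, limma-voom, the replicate block, non-treated as the control and each left-out library. Both controls together, fits of the 6 libraries compared, other filters and other forms of the trend were not counted. Rows without an adjusted p, 5 in all, were left out. Of the 216, 171 kept direction and call under every counted alternative run for their comparison. The other 45 lost the call under at least 1 of these alternatives, namely 15 of 26 called genes for vehicle against non-treated, 11 of 18 at 20, 12 of 44 at 100 and 5 of 83 at 500 µg/mL, 2 of 35 for the trend, 0 of 1 from 20 to 100 and 0 of 9 from 100 to 500 µg/mL.

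Counts of genes stayed within 1.5 times under RLE, library totals, limma-voom, the CPM filter, the replicate block and a slope on the dose itself (3330 for the trend), but moved more in the cases given here. Without a low-count filter 73 genes were called at JGT 20 µg/mL. By DESeq2, 319 were called for vehicle against non-treated and 95 at 20 µg/mL. With a log2 change of at least 1, the counts were 1 for vehicle against non-treated, 1, 24 and 391 at 20, 100 and 500 µg/mL, 2 from 20 to 100, 152 from 100 to 500 and 26 for the trend, since the setting asks for more. Fitted on the 6 libraries compared only, 1031 genes were called for vehicle against non-treated, 330 at 20, 1369 at 100, 191 from 20 to 100 and 1313 from 100 to 500 µg/mL. With non-treated as the control, 450 were called at 20 and 1320 at 100 µg/mL, 31 and 430 of them shared with the calls against vehicle. With both controls together, 196 and 1144 were called. With vehicle as rank 0, 3892 genes followed the trend, which then holds the step from control to JGT libraries. Grem1 at 20 µg/mL went from 0.30 to −0.0527 (adjusted p = 0.664) and Rps6 at 500 µg/mL from 0.14 to −0.0402 (adjusted p = 0.557) with non-treated as the control. Except where an alternative's own construction is named, the cause was not tested.

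Lists called with an estimated correlation were 1 for vehicle against non-treated, 4, 7 and 8 at 20, 100 and 500 µg/mL and 0 by camera for the trend, where 7 had an unadjusted p under 0.05 and fry called 19. Non-treated as the control gave 9 lists at 20 µg/mL, only 4 of them among the 14 called against vehicle, and 14 at 100 µg/mL, 9 of them among the 14. By fry, 24 were called at 500 µg/mL, 13 of them among the 14. The correlation of the 100 and 500 µg/mL effects was 0.32 or 0.0950 with separate controls, since a shared control adds to it. The cause of the other differences was not tested.

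Leaving out each library in turn gave 36 to 88 genes for vehicle against non-treated, 18 to 36 at 20, 315 to 409 at 100 and 3704 to 6323 at 500 µg/mL, 19 to 41 from 20 to 100, 1880 to 4989 from 100 to 500 and 1374 to 2765 for the trend. The highest counts at 500 µg/mL and from 100 to 500 µg/mL came without JGT 500 replicate 2, and the lowest at 500 µg/mL without replicate 1. Lists ranged from 11 to 13, 11 to 14, 12 to 16, 13 to 16 and 14 to 20, for vehicle against non-treated, 20, 100 and 500 µg/mL and the trend.

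Replicate numbers did not pair the libraries across all groups. Pairs of the same number (1, 2 and 3) lay at 0.0730, 0.106 and 0.116 between JGT 100 and 500 µg/mL. They lay at −0.1785, −0.2099 and 0.0445 between JGT 20 and 500, and at −0.106, −0.0769 and 0.0575 between JGT 20 and 100. Of 30 pairs of libraries with the same number, 4 had a correlation of residuals over 0.1 (lowest −0.324, highest 0.119, median −0.0170), and 3 of 15 libraries correlated best with one of their own number. With the number as a block, 169, 49, 582 and 4757 genes were called for vehicle against non-treated and at 20, 100 and 500 µg/mL, 61 from 20 to 100, 2731 from 100 to 500 and 2097 for the trend, and 12, 13, 13, 14 and 18 lists. The block ended the calls of Isx, Polq, Egr1 and Nr4a1 for vehicle, Mfsd2a and Me1 at 20, Actn2 at 100 µg/mL, Myog for the trend and the histone list at 20 µg/mL (adjusted p = 0.0705), for a cause that was not tested.

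Depth limits the genes near the filter. Mstn had 7 counts in all libraries together and at most 2 in 1 library, so no change was detectable in it.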

Other observations

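The slopes of JGT 500 replicates, the lists named here, their counts without replicate 2 and the simulated correlation over genes with a CPM of at least 1 were chosen only after the result was seen.

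Further groups moved at 500 µg/mL against vehicle. Of 22 genes of xenobiotic transport and conjugation, 11 rose, 9 were not called and 2 fell, the efflux pump Abcb1b (log2 −0.24) and the glutathione transferase Mgst3 (−0.70), while 13 rose and 3 fell when adjusted over the list alone (median 0.23, adjusted p = 2.6e-05, and 0.00648 with an estimated correlation). Beside Aldh3a1, Gstm1 and Ugt1a6a, the alcohol dehydrogenase Adh7 (1.71 ± 0.0650) had the smallest p. Of 28 lysosome genes, 10 rose and 18 were not called, also when adjusted over the list alone (median 0.05, adjusted p = 0.0186, but adjusted p = 0.168 with an estimated correlation), led by the proteases Ctsl (0.37), Ctsd (0.27) and Ctsb (0.23) and by Psap (0.38). Without JGT 500 replicate 2, 12 xenobiotic genes rose and 2 fell, and 10 lysosome genes rose and 3 fell, while the lysosome list was not called (adjusted p = 0.169).

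Of 26 genes of ribosome biogenesis and MYC targets, 12 fell, 13 were not called and Odc1 rose (0.20), while 13 fell and 1 rose when adjusted over the list alone (median −0.10, adjusted p = 0.0112, but adjusted p = 0.323 with an estimated correlation). The spermidine synthase Srm (−0.47), Ppan (−0.48), Cad (−0.25) and Polr1b (−0.22) fell, the last not against non-treated libraries (−0.12, adjusted p = 0.0749). Of 54 cytosolic ribosomal protein genes, 6 fell, 47 were not called and Rps6 rose (0.14), while 2 fell when adjusted over the list alone (median −0.09, adjusted p = 0.0217, but adjusted p = 0.545 with an estimated correlation). Rps16 (−0.21), Rps19 (−0.24) and Rpl13 (−0.20) fell, and processed copies of these genes make their counts uncertain. The list was not called without vehicle replicate 2 (adjusted p = 0.0757), vehicle replicate 3 (0.0565) or JGT 500 replicate 1 (0.111). Against non-treated libraries, the adjusted p was 0.0842 for Rpl13 and 0.557 for Rps6 (−0.0402). Without vehicle replicate 2 or 3 or JGT 500 replicate 1 or 3 it was 0.075, 0.0745, 0.101 and 0.103 for Rpl13 and 0.0691, 0.107, 0.144 and 0.142 for Rps6, in that order. Without JGT 500 replicate 2, 11 biogenesis genes fell and 3 rose, the biogenesis list was not called (adjusted p = 0.226), and 27 ribosomal protein genes fell and 5 rose, a count that this library decides.

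Fold changes at 100 and 500 µg/mL against the same vehicle libraries had a correlation of 0.61 across genes, which are not independent replicates. Simulated groups with no effect gave 0.535 (SD 0.0472) from the shared vehicle alone. The covariance was 0.0733 against a simulated 0.0282, an excess of 0.0451, and the gene model Gm20388 alone made up 11.8% of the covariance. The next largest shares, 6.43%, 3.93%, 3.00% and 2.27%, belonged to Gm28048, Gm29542, Gm20775 and Gm26635, each at a mean of at most 0.972 CPM. Genes near the filter thus weigh heavily in these values. Vehicle for 1 dose and non-treated for the other gave 0.32 or 0.0950, against −0.00528 (SD 0.0929) in simulated groups with no effect, so the lower correlation is within about its spread of no relation. The covariances of these pairings were 0.0347 and 0.0120, both beyond the simulated spread (−0.000367, SD 0.00505). Among genes with a CPM of at least 1 in 3 libraries the correlation was 0.635, against 0.541 simulated. Calls of comparisons that share no library were compared. They come from 1 fit of all libraries, and both comparisons hold any difference between the code series. An overlap above that of independent lists is therefore not by itself a shared effect of the doses. Of the 302 genes higher at 100 µg/mL against vehicle, 246 were also higher at 500 against non-treated, where independent lists would share 49.1, and of the 321 lower genes 287, against 49.8, with 6 and 2 called the opposite way. In the other pairing, of the 621 genes higher at 100 µg/mL against non-treated, 345 were higher at 500 against vehicle (102.5 for independent lists), and of the 699 lower genes 515 (117.4), with 43 and 9 called the opposite way. The 100 µg/mL calls against vehicle had the same sign at 500 µg/mL against non-treated in 93.7% of the higher and 96.9% of the lower genes, and the 100 µg/mL calls against non-treated had that sign at 500 µg/mL against vehicle in 81.8% and 90.3%.

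The difference of each JGT 500 library from vehicle was regressed across genes, which are not independent replicates, on the mean difference of the other 2 from non-treated. Replicate 2 gave a slope of 0.548 over all tested genes, against 0.731 and 0.714 for replicates 1 and 3. Over the 1320 genes called at 100 µg/mL against non-treated, the slopes were 0.845, 0.852 and 0.817 for replicates 2, 1 and 3.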
